A study of Mus musculus with 8 samples.

How the data were processed

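Total RNA from cultured peritoneal macrophages of C57BL/6J mice was extracted with a silica column kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The first line of the platform annotation names the array as Mouse Gene 1.0 ST, a whole-transcript design whose probes lie along each gene. There were 4 arrays of unloaded cells and 4 of cells cultured with acetylated low-density lipoprotein (acLDL). Groups and replicate numbers came from the sample descriptions. The series description calls the 4 arrays of each condition independent biological replicates, without saying which mice contributed to which culture.

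The deposited values are log2 expression values, made with robust multi-array averaging (RMA) per the submitters' processing notes. RMA subtracts background, matches the distributions of the arrays and summarises the probes of each probe set. Its version and settings are not given in the sources used here. The distributions of the 8 arrays were close but not identical, and whether they were normalised alone or within a larger set is not given in the sources used here. RMA compresses differences of dim genes towards 0, and matching distributions hides a change that all genes share.

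The deposited table held 35557 probe sets. The annotation listed 23410 of them, of which 21789 had 1 gene symbol and 1621 had several. The other 12147 were not in the annotation used here and stayed unnamed. Symbols were updated through Entrez identifiers with the RefSeq gene table of assembly GRCm38.p6, which held 21698 of the 21789 probe sets and not the other 91, and 0 symbols changed. No coordinates are given, because the build behind the annotation is not given in the sources used here. Genes with several probe sets, 999 in number, were represented by the probe set with the highest mean over the 8 arrays, which left 19938 genes for testing. The annotation does not mark control probe sets, so the alternative of testing every non-control probe set used all 23410 annotated ones. The planned check of the control probe sets for 3 prime and 5 prime ends could not be run for the same reason.

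Differences were coded as acLDL minus unloaded and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. A second count required a change of at least 1.5-fold. The fit had no block, since nothing in the labels ties equal replicate numbers to a shared mouse or day. Before the data were examined, 30 gene lists were fixed, 8 of them markers of other cells. Each was tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and adjustment over the 30 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, stood beside it. Of 607 list members, 554 entries were measured by a probe set with 1 symbol, and the rest were not analysed here. Some genes belong to more than 1 list.

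Genes were named by a rule fixed beforehand. It took the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap. It also took up to 4 members of each list with the largest change past the threshold. For each list of other cells it took the member with the smallest p and the brightest member. The rule gave 105 genes. Srebf1, Plin2, Cd36, C1s1, Cd14, Csf1r, Lyz2, Pcna, Sdha, Cd3e, Sparc, Malat1, Xist, Tug1 and the named small RNAs fall outside it and were chosen after their values were seen. Single values per array, such as medians, were compared with a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 arrays against 4 can give.

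Alternatives fixed beforehand were a replicate block, all annotated probe sets, the mean of a gene's probe sets, a filter on dim genes, repeated quantile normalisation, median centring, a trended robust prior, array weights, the other list tests and leaving out each array in turn. Alternatives chosen after seeing the data were all deposited probe sets, cyclic loess, removal of a trend with genomic span, leaving out pairs of unloaded arrays and a filter at the level of olfactory receptor genes. A result below the threshold in both settings was counted as unaltered even where its sign changed. The limma step was tested on simulated arrays with the spread of this comparison, in which 200 of 19938 genes were changed. It recovered 86% of genes changed by 1.5-fold and 100% of those changed by 2-fold, 3-fold or 6-fold, with 11 false calls (5.4% of calls). Genes were simulated independently and without any array-wide effect, so the share of false calls may differ in the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Precision is limited by the number of arrays, and the median standard error of a log2 difference was 0.074.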

Results

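Gene expression was measured in macrophages that enter the peritoneal cavity of mice after an injection of thioglycollate, an irritant broth, and that were harvested 5 days later. The cells were cultured with or without acLDL, a chemically modified lipoprotein that macrophages take up through scavenger receptors and that loads them with cholesterol. The labels disagree on the exposure. The sample protocols give 3 days with 20 µg/mL acLDL and the series description gives 2 days with 50 µg/mL, so the dose and time behind the values below are not settled. Deposited log2 values of the 4 unloaded and 4 acLDL arrays ran from 2.63 to 14.27.

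Arrays of one group resembled each other more than arrays of different groups. Pearson correlations across genes were 0.990 to 0.995 within groups and 0.982 to 0.988 between groups, and 0 pairs of arrays were identical. The first principal component held 53.5% of the variance and separated the groups. The second held 18.0% and separated unloaded arrays 1 and 4 from unloaded arrays 2 and 3. Array medians were 6.30 ± 0.06 (SD, n = 4) in unloaded and 6.27 ± 0.02 (SD, n = 4) in acLDL cells. Olfactory receptor genes, which macrophages are not known to use, served as a measure of background chosen after seeing the data. Their median level was 4.46 ± 0.04 (SD, n = 4) in unloaded and 4.39 ± 0.02 (SD, n = 4) in acLDL arrays (exact permutation p = 0.0286, the smallest possible; 0.114 after Benjamini-Hochberg adjustment over 4 array measures).

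**Figure D1:**
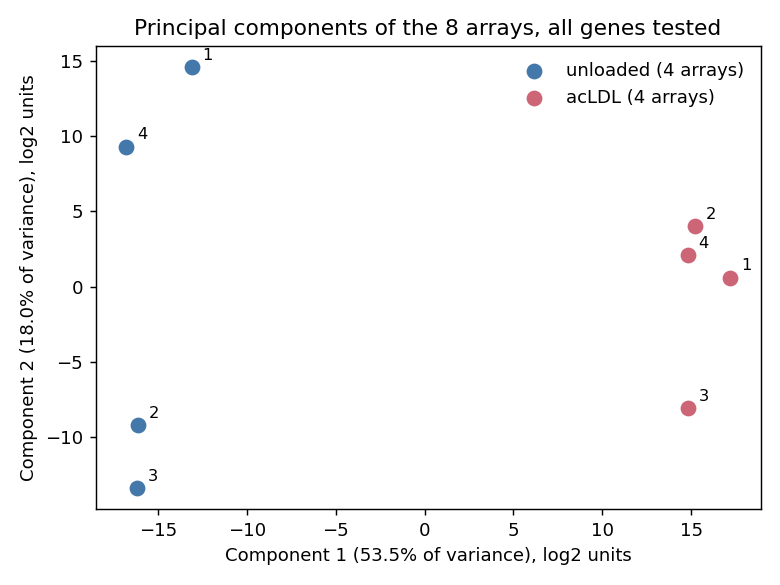
Position of each array on the first and second principal components of all tested genes, in log2 units, with replicate numbers beside the points. Unloaded arrays (blue) lie between -16.8 and -13.1 on component 1 and acLDL arrays (red) between 14.8 and 17.2.

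The comparison asked which genes macrophages express at other levels when loaded with acLDL. Genes of cholesterol synthesis fell the furthest. Idi1, which isomerises isopentenyl diphosphate, was 5.47-fold lower, from 9.24 ± 0.13 to 6.79 ± 0.10 (log2, SD, n = 4). Cyp51, the lanosterol demethylase, was 5.05-fold lower, from 9.27 ± 0.12 to 6.94 ± 0.14 (log2, SD, n = 4). The largest rise was in Cd5l, a secreted scavenger receptor cysteine-rich protein of macrophages, which was 7.61-fold higher at 9.51 ± 0.07 against 6.58 ± 0.32 (log2, SD, n = 4).

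The next largest rises were in Folr2, a folate receptor (log2 difference 1.93 ± 0.07 SE), Gstp1, a glutathione transferase (1.93 ± 0.12 SE), and Abca1, the cholesterol exporter (1.93 ± 0.06 SE). C1qa, C1qb, the properdin gene Cfp and the scavenger receptor gene Stab1 followed, with log2 differences of 1.70, 1.52, 1.47 and 1.43. The Gstp1 value is uncertain, since mice carry a near-identical copy, Gstp2, that its probes may not distinguish. After Idi1 and Cyp51, the largest falls were in Sc5d, Sqle, Insig1, Hmgcs1, Fdft1 and Lss, with log2 differences of -1.90, -1.88, -1.66, -1.63, -1.56 and -1.46. The rule that named these 16 genes required the 4 acLDL arrays to lie apart from the 4 unloaded arrays. The largest limma adjusted p among them was 2.05e-07, for Gstp1.

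**Figure D2:**
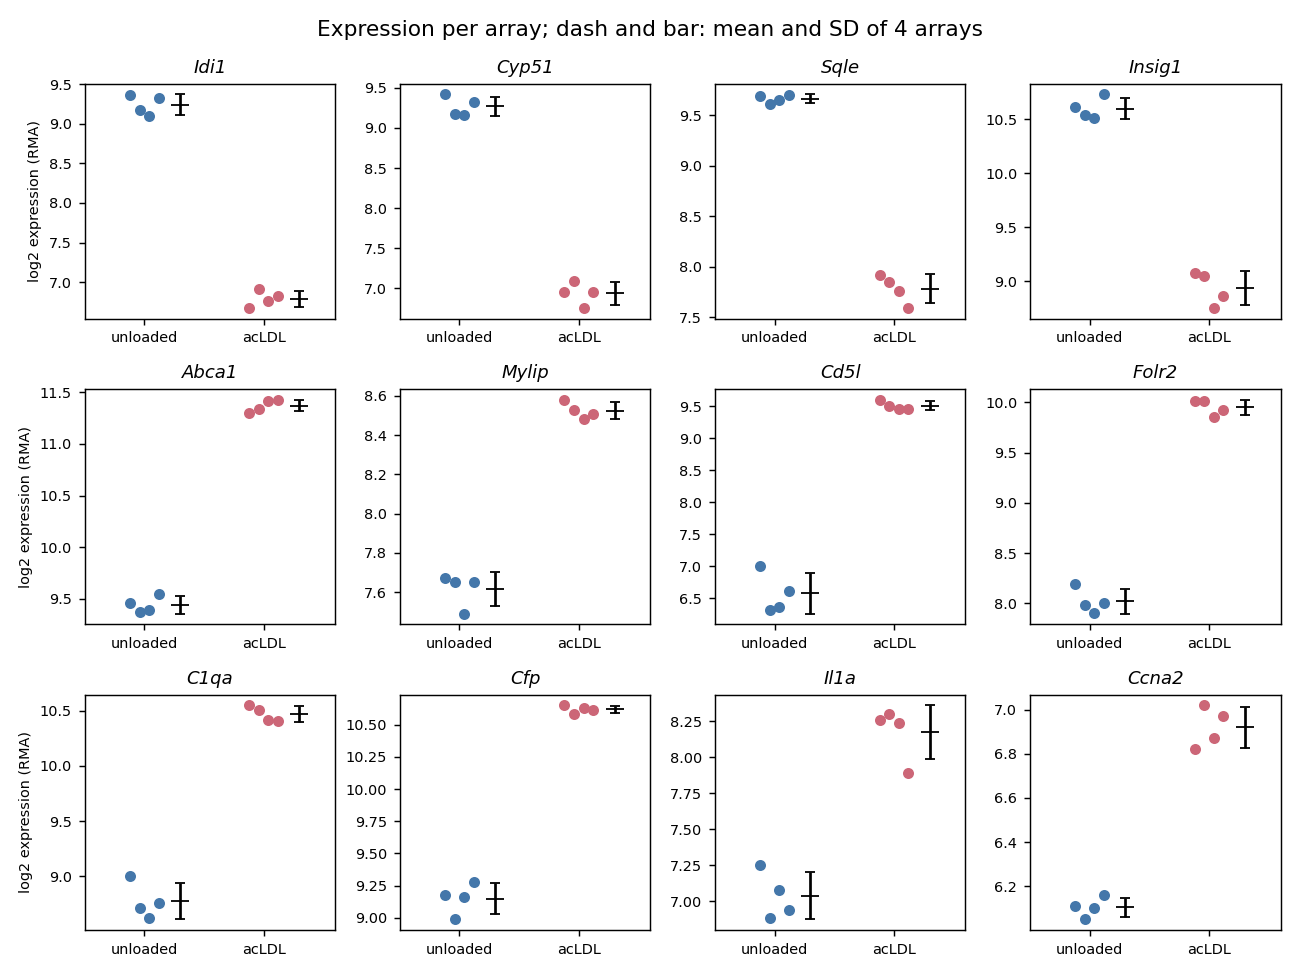
Log2 expression of 12 named genes in each unloaded (blue) and acLDL (red) array, with the mean and SD of 4 arrays beside the points and a separate vertical scale for each gene. Idi1 fell by 2.45 and Cd5l rose by 2.93 on the log2 scale.

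Of 19938 genes, 4650 (23.3%) changed at an adjusted p under 0.05 in limma, 2565 higher and 2085 lower with acLDL. Most changes were small. The median absolute log2 difference of the changed genes was 0.313, and 405 genes changed by at least 1.5-fold (266 higher, 139 lower) and 61 by at least 2-fold (39 higher, 22 lower). The groups did not overlap in 5101 genes (25.6%), against 2.86% by chance. Centring each array on its median gave 4192 genes, 2802 higher and 1390 lower, so that the share of rises was 66.8% in place of 55.2%. Testing all deposited probe sets, unnamed ones included, turned the balance of changes of at least 1.5-fold to 589 higher and 935 lower, an alternative chosen after seeing the data. The balance of these larger changes also turned with the unloaded arrays used, being 394 higher and 118 lower without arrays 1 and 4, and 199 higher and 231 lower without arrays 2 and 3.

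Sterol synthesis genes fell together. Of 22 measured members of the list of sterol synthesis and uptake genes, which the transcription factor SREBP2 controls, 0 rose, 19 fell and 3 did not pass in limma, and 20 fell when adjusted over the list alone. The median log2 difference was -1.34, and the list was lower than other genes (camera adjusted p = 7.21e-29; adjusted p = 0.0504 with an estimated correlation). Insig1, which retains the SREBP complex in the endoplasmic reticulum, went from 10.60 ± 0.10 to 8.94 ± 0.16, and Sqle, the squalene epoxidase, from 9.66 ± 0.04 to 7.78 ± 0.14 (log2, SD, n = 4). Fatty acid synthesis and desaturation genes fell in part. In that list 1 of 17 members rose, 10 fell and 6 did not pass, 11 changed (1 higher, 10 lower) when adjusted over the list alone, and the median was -0.24 (camera adjusted p = 1.50e-05; adjusted p = 0.246 with an estimated correlation). Fads2 and Scd1, which are fatty acid desaturases, fell by 0.94 and 0.77 on the log2 scale, and the elongase gene Elovl6 fell by 0.80. The member that rose was Srebf1, which encodes the transcription factor SREBP1, by 0.21 ± 0.06 (log2, SE; limma adjusted p = 0.0189).

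In the list of targets of the liver X receptors (LXR), nuclear receptors for oxysterols, and of cholesterol efflux genes, most members rose. Of 16 measured targets and efflux genes 11 rose, 0 fell and 5 did not pass, 12 changed (11 higher, 1 lower) when adjusted over the list alone, and the median log2 difference was 0.33 (camera adjusted p = 9.24e-07; adjusted p = 0.203 with an estimated correlation). Abca1 was 3.81-fold higher, at 11.37 ± 0.06 against 9.44 ± 0.08 (log2, SD, n = 4). Mylip, whose product marks lipoprotein receptors for degradation, was 1.88-fold higher, and the exporter gene Abcg1 1.46-fold, and the LXR alpha gene Nr1h3 rose by 0.66 on the log2 scale. Srebf1, also an LXR target, is the gene described among the fatty acid genes. The LXR list shares no other member with the fatty acid list, in which 10 of 17 fell.

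Genes of lipid uptake and storage went both ways or did not pass. Among 18 scavenger and lipoprotein receptors 3 rose, 3 fell and 12 did not pass, 9 changed (5 higher, 4 lower) when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.728). Stab1 and Msr1, encoding the class A scavenger receptor for acLDL, rose by 1.43 and 0.56, and Cxcl16 and Fcgr2b fell by 0.60 and 0.39 on the log2 scale. Cd36, a receptor for oxidised lipoprotein, differed by 0.06 ± 0.06 (log2, moderated SE, limma adjusted p = 0.448) and did not pass. Its groups did not overlap, at 12.87 ± 0.01 in unloaded and 12.93 ± 0.01 in acLDL cells (log2, SD, n = 4). Among 20 lipid droplet and cholesteryl ester genes 1 rose, 2 fell and 17 did not pass, 3 changed (1 higher, 2 lower) when adjusted over the list alone, and camera gave an adjusted p of 0.880. The list members Soat1 and Soat2 were not measured by a probe set with 1 symbol and were not tested. Mgll, a monoacylglycerol lipase, rose by 0.50 and Lipa, the lysosomal acid lipase, fell by 0.27 on the log2 scale. The lipid droplet coat gene Plin2 stood at 12.33 ± 0.06 and 12.34 ± 0.03 (log2, SD, n = 4) in unloaded and acLDL cells.

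Among 21 targets of the PPAR receptors and fatty acid oxidation genes 4 rose, 4 fell and 13 did not pass, 8 changed (4 higher, 4 lower) when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.745). Eci1 and Crat rose by 0.48 and 0.46 on the log2 scale, while Etfdh and the receptor gene Pparg fell by 0.41 and 0.33. Of 29 lysosome genes 4 rose, 7 fell and 18 did not pass, and 11 changed (4 higher, 7 lower) when adjusted over the list alone (camera adjusted p = 0.258). The transcription factor genes Tfe3 and Tfeb rose by 0.37 and 0.34, and Asah1, an acid ceramidase, and Atp6v1a, a proton pump subunit, fell by 0.39 and 0.29 on the log2 scale. Camera's adjusted p for the lysosome list fell below the threshold after repeated quantile normalisation (0.0284), after cyclic loess (0.0385) and without unloaded arrays 2 and 3 (0.0478), the last pair of settings chosen after seeing the data.

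Complement genes rose in part, led by the subunits of C1q, which starts the classical pathway. Of 22 measured members 8 rose, 1 fell and 13 did not pass, 9 changed (8 higher, 1 lower) when adjusted over the list alone, and the median log2 difference was 0.10 (camera adjusted p = 0.000328; adjusted p = 0.340 with an estimated correlation). C1qa, C1qb and C1qc were 3.25-fold, 2.87-fold and 2.63-fold higher, and Cfp, encoding properdin of the alternative pathway, was 2.77-fold higher. C1s1 fell by 0.36 on the log2 scale. Among 16 macrophage identity genes 8 rose, 1 fell and 7 did not pass, and 12 changed (8 higher, 4 lower) when adjusted over the list alone. The median was 0.16 (camera adjusted p = 0.0235; adjusted p = 0.618 with an estimated correlation), and the call was lost without unloaded array 3 (adjusted p = 0.0884), after repeated quantile normalisation (0.115) and in 4 other settings with an adjusted p of up to 0.310. The Fc receptor genes Fcgr1 and Fcgr3 rose by 0.71 and 0.59, Itgam by 0.63 and Adgre1, which encodes F4/80, by 0.59 on the log2 scale. Cd14 fell by 0.33, and Csf1r and Lyz2 differed by 0.00 ± 0.06 and 0.06 ± 0.06 (log2, SE), which did not pass.

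Lists of macrophage states did not shift as wholes. Of 18 genes of alternative activation 4 rose, 3 fell and 11 did not pass, and 8 changed (4 higher, 4 lower) when adjusted over the list alone (camera adjusted p = 0.993, with a negative median and a positive mean). Clec10a, a galactose-type lectin, rose by 1.10 and Arg1, the arginase gene, by 0.59, from unloaded levels of 5.07 and 5.66, which lie below 6.12, the 95th percentile of the olfactory receptor genes, so that the sizes may be understated, and Clec7a, the beta-glucan receptor gene, fell by 0.66 on the log2 scale. In the list of lipid-associated macrophage genes 5 of 15 members rose, 2 fell and 8 did not pass, and 8 changed (6 higher, 2 lower) when adjusted over the list alone (camera adjusted p = 0.506, with a negative median and a positive mean). Trem2, a lipid-sensing receptor, rose by 0.51, Apoe and Lpl by 0.33 each, and Cd63 fell by 0.27 on the log2 scale. Among 14 markers of resident large peritoneal macrophages 3 rose, 1 fell and 10 did not pass, and 4 changed (3 higher, 1 lower) when adjusted over the list alone (camera adjusted p = 0.304). Vsig4, a complement receptor gene, was 1.86-fold higher and Cxcl13 was 1.52-fold lower.

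Matrix proteases and their inhibitors went both ways. Of 25 members 6 rose, 7 fell and 12 did not pass, and 16 changed (8 higher, 8 lower) when adjusted over the list alone (camera adjusted p = 0.993, with a negative median and a positive mean). Plau, the urokinase gene, was 2.18-fold higher, Mmp9 1.88-fold and Adam8 1.54-fold. Of 10 genes of MHC class II and costimulation 2 rose, 2 fell and 6 did not pass, and 4 changed (2 higher, 2 lower) when adjusted over the list alone (camera adjusted p = 0.863). H2-Aa and H2-Eb1, chains of the class II molecules, fell by 0.60 and 0.39, and Cd83 rose by 0.33 on the log2 scale.

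Inflammatory genes rose in part. Of 26 NF-kB genes 11 rose, 3 fell and 12 did not pass, 17 changed (12 higher, 5 lower) when adjusted over the list alone, and the median log2 difference was 0.17 (camera adjusted p = 0.00300; adjusted p = 0.246 with an estimated correlation). Il1a, encoding interleukin-1 alpha, was 2.20-fold higher, the chemokine gene Ccl5 1.80-fold, Acod1, which makes itaconate, 1.78-fold and Saa3 1.72-fold. The 3 that fell, Il1rn, Nos2 and Il6, did so by 0.40, 0.33 and 0.21 on the log2 scale, were chosen for mention after their values were seen, and the levels of Nos2 and Il6 were below 6.12, the 95th percentile of the olfactory receptor genes. Of 23 genes of the type I interferon response 13 rose, 0 fell and 10 did not pass, 14 changed (14 higher, 0 lower) when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 1.26e-06; adjusted p = 0.241 with an estimated correlation). Cmpk2, Ifit1, Ifit3 and Ifit2 were 1.97-fold, 1.92-fold, 1.90-fold and 1.80-fold higher, from unloaded levels of 5.25 to 6.58. Ifit3 and Ifit2 lay at or below 6.12 in unloaded cells, so that their folds may be understated.

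Stress genes also rose in part. Of 22 NRF2 and oxidative stress genes 11 rose, 0 fell and 11 did not pass, 12 changed (12 higher, 0 lower) when adjusted over the list alone, and the median log2 difference was 0.18 (camera adjusted p = 3.90e-05; adjusted p = 0.340 with an estimated correlation). Blvrb, a biliverdin reductase, was 2.02-fold higher, and Hmox1, the heme oxygenase gene, and Gclm, of glutathione synthesis, were 1.45-fold higher. Of 24 genes of the unfolded protein and integrated stress responses 7 rose, 3 fell and 14 did not pass, and 12 changed (9 higher, 3 lower) when adjusted over the list alone (camera adjusted p = 0.126, 0.0422 without unloaded array 4, and 0.00782 without unloaded arrays 1 and 4, a pair left out after seeing the data). Asns, the asparagine synthetase gene, was 2.22-fold higher, Sdf2l1 1.61-fold, Sesn2 1.53-fold and Trib3 1.38-fold.

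Cell cycle genes rose together, and by their mean over all arrays 22 of 29 lay above 6.12, the 95th percentile of the olfactory receptor genes. Of 29 members 23 rose, 1 fell and 5 did not pass, 28 changed (27 higher, 1 lower) when adjusted over the list alone, and the median log2 difference was 0.35 (camera adjusted p = 3.45e-12; adjusted p = 0.0504 with an estimated correlation). Ccna2, encoding cyclin A2, went from 6.10 ± 0.04 to 6.92 ± 0.09, Top2a from 6.19 ± 0.10 to 6.88 ± 0.10 and Mki67 from 6.39 ± 0.19 to 7.07 ± 0.06 (log2, SD, n = 4). The unloaded level of Ccna2 lay below 6.12, so that its change may be understated. The member that fell was Pcna, by 0.19. Of 21 oxidative phosphorylation genes 10 rose, 1 fell and 10 did not pass, 11 changed (10 higher, 1 lower) when adjusted over the list alone, and the median was 0.14 (camera adjusted p = 0.000881; adjusted p = 0.618 with an estimated correlation). Without unloaded arrays 2 and 3, a setting chosen after seeing the data, the camera adjusted p of this list was 0.123. Its median ran from 0.10 to 0.20 when each array was left out in turn. Ndufb8, Sdhb, Ndufv1 and Uqcrc1 rose by 0.54, 0.51, 0.45 and 0.42, and Sdha fell by 0.19 on the log2 scale.

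Of 17 ribosome and translation genes 7 rose, 2 fell and 8 did not pass, and 12 changed (8 higher, 4 lower) when adjusted over the list alone (camera adjusted p = 0.162). Rpl27 and Rpl13 rose by 0.66 and 0.50 on the log2 scale. Signal also varied with gene length, gauged in the 11627 genes above the olfactory 95th percentile that had a genomic span. The Spearman correlation across these genes of each array's deviation with span was 0.23, -0.02, -0.05 and 0.21 in unloaded arrays 1 to 4. It was -0.12, -0.05, -0.20 and -0.01 in acLDL arrays 1 to 4. Group means were 0.091 ± 0.149 and -0.095 ± 0.083 (SD, n = 4; exact permutation p = 0.114, and 0.229 after Benjamini-Hochberg adjustment over 4 array measures). The log2 difference itself had a Spearman correlation of -0.12 with span across these genes, so that the shorter of them tended to be higher with acLDL. Genes are not independent replicates in such a correlation. The olfactory receptor genes, mostly dimmer and with a median span of 0.95 kb, went the other way (median log2 difference -0.079). Of 21 genes of glycolysis and hypoxia 2 rose, 3 fell and 16 did not pass, and 5 changed (2 higher, 3 lower) when adjusted over the list alone (camera adjusted p = 0.993, with a positive median and a negative mean). Pdk1 rose by 0.46, and Slc16a3, a lactate exporter gene, fell by 0.51 on the log2 scale.

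**Figure D3:**
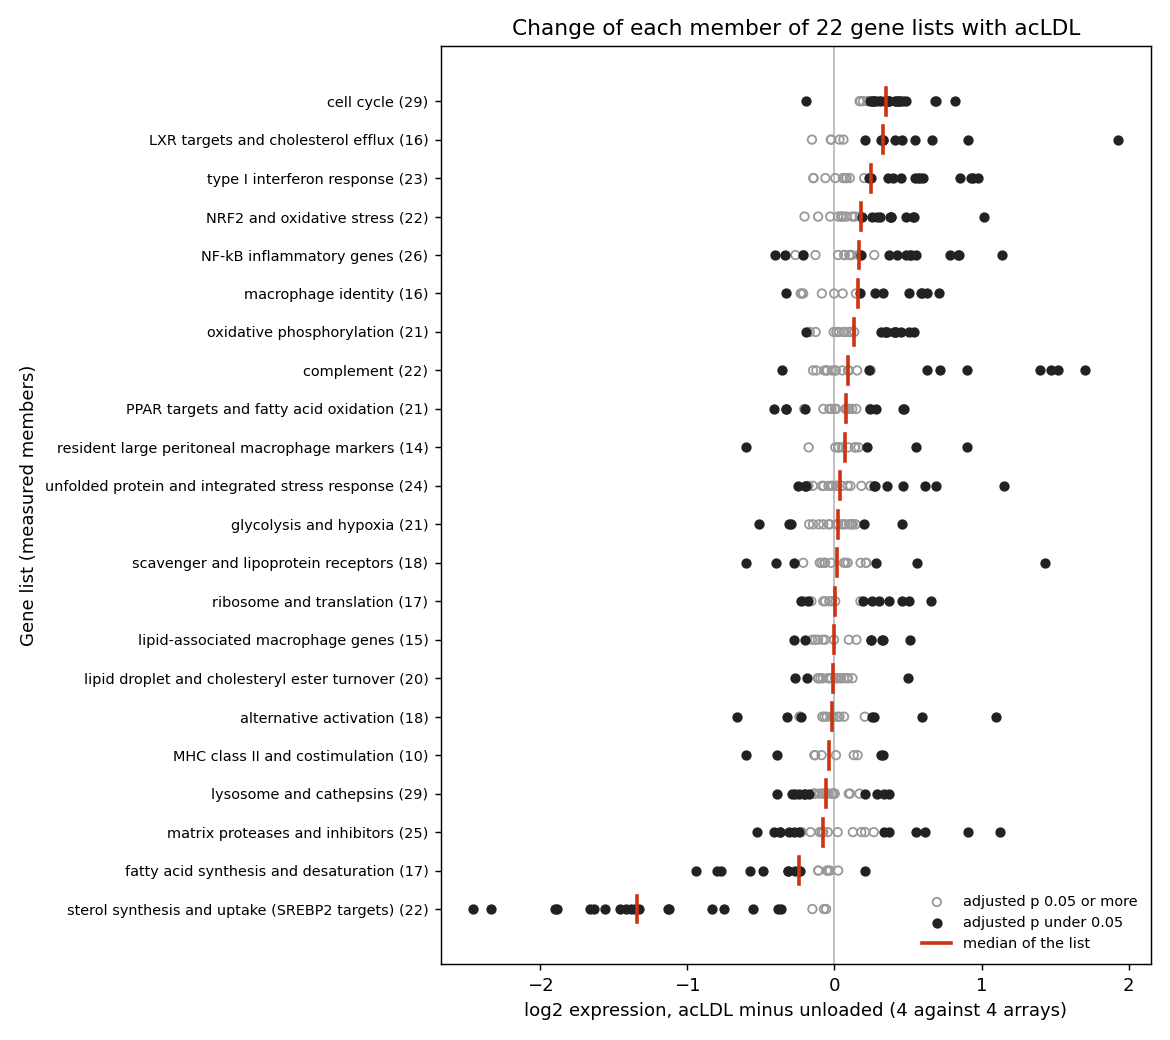
Log2 difference, acLDL minus unloaded, of each measured member of the 22 lists that are not markers of other cells, with members past an adjusted p of 0.05 filled and the median as a red line. Medians run from -1.34 for sterol synthesis to 0.35 for the cell cycle.

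Markers of other cells were mostly dim, except those of mesothelial cells and fibroblasts, and most did not pass. Of 108 markers in 8 lists 2 rose, 17 fell and 89 did not pass, and 70 lay at or below 6.12, the 95th percentile of the olfactory receptor genes. Of these 8 lists the T and NK cell list passed, with 4 of 17 members lower, 4 when adjusted over the list alone, and a median of -0.08 (camera adjusted p = 0.0338; adjusted p = 0.618 with an estimated correlation). This call was lost without unloaded array 2, unloaded array 3, acLDL array 2 or acLDL array 4 (adjusted p = 0.148, 0.0846, 0.0718 and 0.0841) and in 5 settings of normalisation, filter or arrays, with an adjusted p of up to 0.477. Its brightest member Il7r, the interleukin-7 receptor gene, went from 12.22 ± 0.01 to 11.60 ± 0.04, while the T cell gene Cd3e stood at 6.47 ± 0.10 and 6.35 ± 0.08 (log2, SD, n = 4). The background set by the olfactory receptor genes was lower in acLDL arrays by 0.08 in the median as well, the olfactory genes' median log2 difference being -0.079.

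Neutrophil markers fell in 3 of 14 genes and 3 when adjusted over the list alone (camera adjusted p = 0.148), and B cell markers in 2 of 11 and 2 when adjusted over the list alone (camera adjusted p = 0.880, with a positive median and a negative mean). Of 17 mast cell, basophil and eosinophil markers 2 fell, 2 when adjusted over the list alone, among them Siglecf, a sialic acid receptor gene, from 7.97 ± 0.13 to 7.37 ± 0.09 (log2, SD, n = 4; camera adjusted p = 0.438 for the list). Of 13 dendritic cell markers 1 rose, 1 when adjusted over the list alone, which was Bst2, also a member of the interferon list (camera adjusted p = 0.770). Of 18 mesothelial and fibroblast markers 1 rose and 2 fell, 5 changed (2 higher, 3 lower) when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.993, with a positive median and a negative mean). Of these 18 markers 12 lay above 6.12. Col1a2, a collagen chain gene, fell by 0.37 from 9.67 and Dcn by 0.26 from 10.74, while Sparc rose by 0.30 on the log2 scale. Of 6 erythroid and platelet markers 1 fell, 1 when adjusted over the list alone (camera adjusted p = 0.95, with a positive median and a negative mean). Of 12 endothelial and adipocyte markers 3 fell, 3 when adjusted over the list alone, among them Vwf, the von Willebrand factor gene, by 0.55 on the log2 scale (camera adjusted p = 0.290 and median -0.05 for the list). The median of this list ran from -0.09 to 0.03 when each array was left out in turn. With genes up to the olfactory 95th percentile left out, a setting chosen after seeing the data, the 4 remaining members of this list had a median of -0.26 and a camera adjusted p of 0.0422.

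Of the 30 lists, 11 passed in camera, 8 higher and 3 lower. With an estimated correlation 0 passed in limma's camera, 6 had an unadjusted p under 0.05, and fry in limma called 18. The 7 lists that passed in fry and not in camera were scavenger receptors, unfolded protein and integrated stress, lipid-associated macrophages, resident macrophages, ribosome and translation, neutrophils, and mast cells with basophils and eosinophils.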

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

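The tests on olfactory receptor genes, which bear on background, were chosen after the result was seen, while those on other splits of the arrays were planned. Of 218 groups of 4 values of the named genes and array measures, 14 (6.42%) held an array far from the other 3, and chance gives about 1 in 20. In acLDL cells array 3 stood apart for C1qb at 11.12 against 11.18 in the others and for Lipa at 12.46 against 12.42. Array 4 stood apart for Eci1 at 7.54, Il1a at 7.89, Ccl5 at 8.78 and Retnla at 4.13, and array 1 for H2-Eb1 at 7.96 and Bst2 at 8.91. In unloaded cells array 1 stood apart for Gclm at 9.09 and Fcgr3 at 9.88, and array 2 for Ifit2 at 5.80 and Plau at 8.89. Array 3 stood apart for Mylip at 7.49 and array 4 for Acod1 at 8.31. All are log2 levels.

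Probe sets outside the comparison changed too. In limma over all deposited probe sets, 2521 of the 12147 unlisted ones (20.8%) changed, 824 higher and 1697 lower with acLDL. Of the 1621 with several gene symbols 622 (38.4%) changed, 247 higher and 375 lower. What the unlisted probe sets measure is not analysed here.

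For the counts of genes, chance assignment of arrays to groups was unlikely, with 1 of 35 splits as the smallest share possible. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 4650 changed genes, the real one, and the highest other split gave 0. The same held for the 405 genes changed by at least 1.5-fold, with 1 split as large and 0 in the highest other. A split that mixes the groups moves their difference into the spread within groups, so the 0 adds little beyond this rank. For the count of 11 lists past the threshold the splits did not exclude chance, because 7 of the 35 gave as many and the highest other gave 13. The 6 others all exchanged 1 array of each group, and the splits that exchanged 2 arrays of each group gave at most 7. Splits that exchange 1 array keep part of the real difference between the groups, so the count of lists cannot decide the question. Taken by its own unadjusted camera p, 1 of 35 splits was as strong as the real one for each of the sterol, LXR, fatty acid, complement and cell cycle lists. It was 3 of 35 for each of the NF-kB, interferon and NRF2 lists, 4 for macrophage identity, 9 for oxidative phosphorylation and 11 for T and NK cells.

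Dim genes carried small falls. Of 1027 olfactory receptor genes 129 (12.6%) changed in limma, 121 of them lower, from a median level of 4.44, and falls were the majority under repeated quantile normalisation (63 of 87), median centring (71 of 82) and cyclic loess (85 of 101). Leaving out 1 array gave from 78 calls, 72 of them lower (without acLDL array 2), to 147, 140 of them lower (without unloaded array 1). A background level or normalisation that differs between the groups' arrays may account for these falls, and calls of small falls near that level are open to it. Calls near background are not the whole of the 4650 changed genes, since 3909 of the 11653 genes above the olfactory 95th percentile changed (33.5%). A difference of normalisation can act on brighter genes too, so this share cannot exclude it. A true fall of olfactory receptor transcripts with acLDL was not tested apart from a lower background, because the arrays with the lower background are the acLDL arrays.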

How the results depend on the processing

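The settings without unloaded pairs, with all deposited probe sets, cyclic loess, the length trend removed or the olfactory filter were chosen after the result was seen. No named gene or list past the threshold reversed in any alternative run, and 96 of 102 named genes past the threshold stayed past it in every one that tested them; Dcn, Gata6, Ighm, Ly6g, Plin3 and Ppbp did not. The filters at the median gene and at the olfactory level tested 98 and 99 of the 105 named genes and 25 and 28 of the 30 lists. Beside the 4650 changed genes, 7603 probe sets changed (3565 higher, 4038 lower) when all deposited ones were tested, a count of probe sets and not of genes. Beside the 405 genes changed by at least 1.5-fold, 624 probe sets (377 higher, 247 lower) changed as much over all annotated ones. Over all deposited ones 1524 probe sets did (589 higher, 935 lower). The balance turned in the last of these settings through the unlisted probe sets, with 216 higher and 689 lower at 1.5-fold, against 321 and 174 among those with 1 symbol. Of the 11 lists 0 passed with an estimated correlation, which allows for genes moving together, and 18 passed in fry, which asks another question; 11 of those were among them. Leaving out each array in turn gave 3618 to 4590 genes, 390 to 465 at 1.5-fold and 9 to 12 lists. Without unloaded arrays 1 and 4 there were 4567 genes and 512 at 1.5-fold, 394 higher and 118 lower, and without unloaded arrays 2 and 3 there were 4669 and 430, 199 higher and 231 lower; the cause was not tested. With the replicate number as a block there were 4860 genes, 405 at 1.5-fold and 11 lists. Nothing in the labels pairs the samples by number. Deviations of same-numbered arrays correlated at 0.11, -0.16, 0.30 and 0.14 across genes, and not every array correlated best with its own number. With so few arrays these values cannot rule pairing out. The block ended the calls of Plin3 and Ppbp among the named genes. Signal near background limits the 8285 genes at or below the olfactory 95th percentile, of which 8.94% changed against 33.5% above it.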

Other observations

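The gene families by symbol, the small RNAs and the tests below were all chosen after the result was seen. Several families of short housekeeping genes were higher by small amounts with acLDL. Of 254 families that share the start of a symbol, 13 were higher and 3 lower in camera with the preset correlation, and 0 of the 16 passed with an estimated correlation in limma (adjusted p = 0.993 with an estimated correlation; 5 had an unadjusted p under 0.05). The 3 lower ones were the olfactory receptor genes (Olfr) that served as background, the Srsf genes and the zinc finger genes (Zfp), whose call was lost without unloaded arrays 1 and 4 (camera adjusted p = 0.148). Of 48 genes of the large subunit of the mitochondrial ribosome (Mrpl) 25 rose and 1 fell, with a median log2 difference of 0.25 (camera adjusted p = 2.00e-08). Of 36 Rpl genes of the cytoplasmic ribosome 18 rose and 1 fell (median 0.20), and of 11 Psmb genes of the proteasome core 9 rose and 0 fell (median 0.41). Among 11 interferon regulatory factor genes (Irf) 8 rose and 0 fell (median 0.31), and among 10 splicing factor genes of the Srsf family 0 rose and 5 fell (median -0.18).

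The long nuclear RNAs Malat1, Xist and Tug1 fell by 1.24, 0.57 and 0.43 on the log2 scale in limma. Malat1 went from 12.65 ± 0.07 to 11.40 ± 0.10 (log2, SD, n = 4; adjusted p = 6.56e-08). Several small nucleolar RNAs rose, Snord15a by 1.17 and Snord33 by 1.15, while the Cajal body RNA Scarna17 fell by 0.80. Rn7sk, an abundant nuclear RNA, stood at 13.23 ± 0.06 and 13.18 ± 0.04 (log2, SD, n = 4). Of 42 small RNAs above the olfactory 95th percentile 19 rose and 5 fell, with a median of 0.18.

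For the fall of Malat1 beside higher small RNAs, less nuclear RNA in the acLDL samples would lower nuclear small RNAs too. Their median log2 difference was 0.09 over 35 genes (quartiles -0.13 and 0.29), so they did not fall as a set. The long nuclear RNAs Malat1, Xist and Tug1 did fall, and the recovery of small RNAs may differ on its own. The small RNAs therefore cannot exclude less nuclear RNA. Better recovery of small RNAs would raise nearly all of them, and 11.9% fell past the threshold, which argues against it as the whole cause. Columns of the RNeasy type retain small RNAs poorly, so a difference in extraction that acts on some of them may remain, as may an effect of acLDL on these transcripts, and no test here separates these.

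For the 13 rising families, many of them of short genes, a trend of signal with gene length that differs between arrays was weighed, with genomic span, which is not transcript length, as the measure. After each array's trend was removed, 12 of the 13 stayed past the threshold in camera with the preset correlation. The trend was fitted over all genes with a span, dim ones included, while the correlations with span were taken in brighter genes. The fit may leave part of the trend of brighter genes, so this test cannot exclude span for those 12. Without unloaded arrays 1 and 4, whose signal rose with span, 13 stayed past it, which argues against these arrays as the whole cause. The Timm family of mitochondrial import genes lost its call once the trend was removed, from a camera adjusted p of 0.0248 to 0.0602. Its median went from 0.23 (quartiles 0.01 and 0.31) to 0.20 (quartiles -0.02 and 0.31), so span stays open for it too. A trend with transcript length or probe content stays open for all 13. So does a response to acLDL, which is a hypothesis found and tested on the same arrays.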
